A study of Mus musculus with 6 samples.

How the data were processed

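RNA was extracted from 10000 plasma cells per library, sorted from mouse bone marrow as high for CD138 and CD267. It was reverse transcribed and amplified as whole cDNA, and sequencing libraries were made from the amplified cDNA with a transposase kit, per the labels' protocols. PCR copies were not marked with molecular identifiers in the sources used here, so counts include them. The exact 95% intervals given below are binomial intervals over numbers of genes and do not cover the spread between libraries. They take genes as independent, which genes are not, so they may be too narrow. The deposited values are raw counts of reads per gene, made with FastQC 0.11.9, Trim Galore 0.6.7, STAR and featureCounts 2.0.1 on GRCm38, per the submitters' processing notes. The version of STAR, the annotation release and the settings for strand and for reads that map to several places are not given in the sources used here. Genes with near-identical copies, such as immunoglobulin segments, Hspa1a and Hspa1b, hemoglobin genes, and genes with many processed pseudogenes such as Gapdh, are uncertain for that reason. The deposited table also gives each gene's summed exon length in bases and its coordinates, which are the ones printed.

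The table held 55291 genes and every row named a gene. Counts were tested as deposited with edgeR 4.0.16 (R 4.3.3): genes were kept by filterByExpr with a minimum count of 10, which left 10401, library sizes were scaled with TMM factors, and a quasi-likelihood test compared 3 fasted with 3 ad libitum libraries with no covariate. P-values were adjusted with the Benjamini-Hochberg method at a threshold of 0.05. CPM values use the TMM factors, and log2 fold changes are fasted minus ad libitum with their standard errors. The square root of the common dispersion was 0.936. Total counts ranged from 20911826 to 27762375 per library, and 3 counts corresponded to 0.108 to 0.143 CPM.

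Gene lists were tested with camera in limma 3.58.1, two-sided, with a preset inter-gene correlation of 0.01 and adjustment over the lists with at least 5 measured members. There were 34 lists, 23 of functions and 11 of other cell types, of which 29 were tested. The lists, the tests and the rule for naming genes were set before the data were examined. The rule named up to 8 genes per direction by fold change among those past the threshold with a mean of at least 10 CPM and no overlap of the groups, leaving out variable, diversity and joining segments and predicted genes. As none passed, the 5 with the lowest p per direction that met the other conditions were named, as values. It also named up to 3 members per list (2 for other cell types) in order of p, and Sdc1, Tnfrsf13b, Jchain and the immunoglobulin constant-region genes. Part of these are printed. Shares of counts and the effective number of heavy-chain variable segments (the exponential of the Shannon entropy of their counts) were compared with exact two-sided permutation tests, whose smallest p for 3 against 3 libraries is 0.1.

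The gene test was tested on simulated counts with the real genes' means and library sizes, with 200 genes changed. These were picked among genes outside immunoglobulin with a mean of at least 10 CPM, so recovery of genes below that was not measured. The gene test called 0% of genes changed 2-fold, 36.5% changed 4-fold, 87.5% changed 8-fold and 97.5% changed 16-fold, so small changes were not detectable with this spread. With the glycolysis list lowered by 0.5 on the log2 scale, camera called it in 7 of 20 simulations, and in 20 of 20 when lowered by 1. In all simulations genes and libraries were drawn independently. The rates therefore do not cover genes that move together or material shared between libraries, and do not show how reliable the calls on the real data are.

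The alternatives were other size factors, removal of immunoglobulin genes, other filters, DESeq2 1.42.0, limma-voom with and without library quality weights, robust dispersions, a minimum fold change of 1.5, thinning to the smallest library, gene length offsets, the replicate number as a block, an estimated inter-gene correlation, fry, and leaving out each library in turn. Chosen after seeing the data were leaving out ad libitum 2 and fasted 3 together, removing ribosomal RNA genes, length offsets and a block with an estimated correlation for the lists, and DESeq2 and quality weights without fasted 3 (DESeq2 also without both). Sharing of transcripts between libraries was examined through genes with at least 50 counts in 1 library and 0 in all others but 1, and through the lowest ratio of counts over genes above 200 counts.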

Results

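Gene expression was measured by RNA sequencing in plasma cells, the antibody-secreting end stage of the B cell lineage, sorted from the bone marrow of C57BL/6J mice. One group of mice had been fasted for 72 h and the other had fed ad libitum. Each group had 3 libraries, each made from 10000 cells gated as high for CD138 (encoded by Sdc1) and CD267 (encoded by Tnfrsf13b). The total gene count per library lay between 20911826 (ad libitum 2) and 27762375 (fasted 2). Immunoglobulin genes took 67.7% to 73.4% of these counts, which left 6513685 to 7964572 counts per library for all other genes. Ad libitum 2 had the fewest detected genes, 9426, against 11187 to 13983 in the other libraries, and its correlations of log2 CPM across genes with the other libraries lay between 0.613 and 0.699. Fasted 3 correlated with fasted 1 at 0.870 and with fasted 2 at 0.866, whereas fasted 1 and fasted 2 correlated at 0.687. Genes are not independent replicates, so these correlations describe the libraries only. All 51 genes with at least 50 counts in fasted 1 and 0 in every library other than fasted 3 were detected in fasted 3, and so were all 58 such genes of fasted 2. Fasted 3 was therefore not treated as sure to be a separate sample, and p-values that count it as one may be too small. The labels do not say whether the 3 libraries of a group came from separate mice, so the p-values measure the spread between these libraries, which may be technical.

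**Figure D1:**
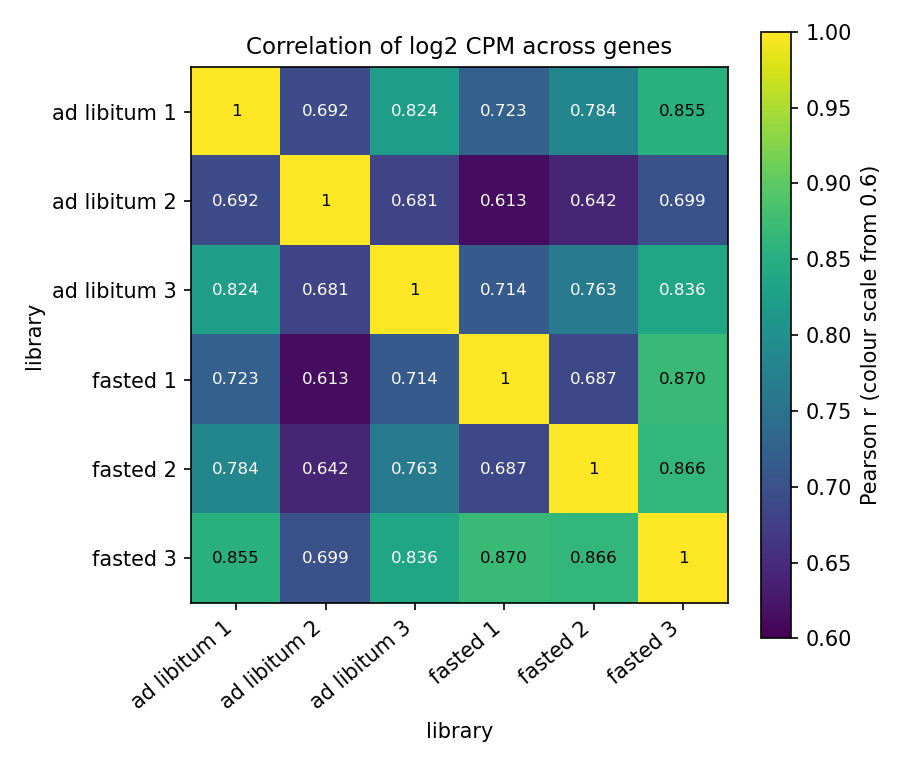
Pearson correlation of log2 CPM across genes for each pair of the 6 libraries, with the library on both axes and the value in each square (colour scale from 0.6 to 1). Fasted 3 correlates with fasted 1 at 0.870 and fasted 2 at 0.866, while fasted 1 and fasted 2 correlate at 0.687. The values of ad libitum 2 lie between 0.613 and 0.699.

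The comparison of fasted with ad libitum libraries asked which transcripts of bone marrow plasma cells differ after 72 h without food. Among the genes with the lowest p, those with more counts in fasted libraries included Sod1, a cytosolic superoxide dismutase (chromosome 16, 90220754 to 90226329), at 84.0 ± 10.2 CPM in ad libitum and 196 ± 10.6 CPM in fasted libraries (SD, n = 3 each). Cirbp, a cold-inducible RNA-binding protein (chromosome 10, 80165985 to 80172786), was at 10.8 ± 5.02 and 57.9 ± 4.69 CPM. The others with more counts were Crip1 (chromosome 12, 113146316 to 113153879; log2 fold change 1.15 ± 0.18 SE), Cyp4f18 (chromosome 8, 71988482 to 72009626; 1.48 ± 0.24) and the linker histone gene H1f0 (chromosome 15, 79028450 to 79030504; 1.33 ± 0.22). With fewer counts in fasted libraries, Hspa1b, an inducible HSP70 chaperone (chromosome 17, 34956436 to 34959238), was at 69.5 ± 24.5 CPM in ad libitum and 9.89 ± 5.63 CPM in fasted libraries. Hspa8, the constitutive HSC70 chaperone (chromosome 9, 40800984 to 40810087), was at 191 ± 49.0 and 81.2 ± 10.8 CPM. Bcat2, a mitochondrial branched-chain amino acid transaminase (chromosome 7, 45570153 to 45589711), had a log2 fold change of -1.43 ± 0.23, and Grn, which encodes progranulin (chromosome 11, 102430315 to 102437048), one of -1.43 ± 0.25. Wnt10a (chromosome 1, 74791516 to 74804179) had one of -1.51 ± 0.26.

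Whether these 10 genes passed depends on the tool: edgeR's quasi-likelihood test with its filter called 0 of them, DESeq2 all 10 and limma's library quality weights 9. Without fasted 3, DESeq2 called 7 of them. It also depends on the filter, since edgeR's test without one called 8 genes, among them Cirbp and Hspa1b (adjusted p = 0.0323 each). Of 10401 genes tested with edgeR, 0 had a Benjamini-Hochberg adjusted p under 0.05, the lowest being 0.380 (Sod1 and Cirbp). At an unadjusted p under 0.05 there were 722 genes, 321 with more and 401 with fewer counts in fasted libraries, where about 520 would be met by chance. The groups did not overlap for 1933 genes (18.6%), against 10% by chance if all libraries are separate samples. If fasted 3 is a mix of fasted 1 and fasted 2, its values tend to lie between theirs. The share met by chance would then be higher than 10%, so no excess is read from this. Other tools gave other counts on the same libraries: 354 genes with DESeq2 (161 higher, 193 lower), 25 with quality weights (7 higher, 18 lower) and 0 with limma-voom. Without fasted 3 these counts were 0 for edgeR, 154 for DESeq2 (22 higher, 132 lower) and 0 with quality weights, and 83 of the 354 DESeq2 genes were called again. Of those 154 genes, 37 were detected in 1 ad libitum library and in no other library of that test. Without both ad libitum 2 and fasted 3, DESeq2 called 144 genes (36 higher, 108 lower).

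**Figure D2:**
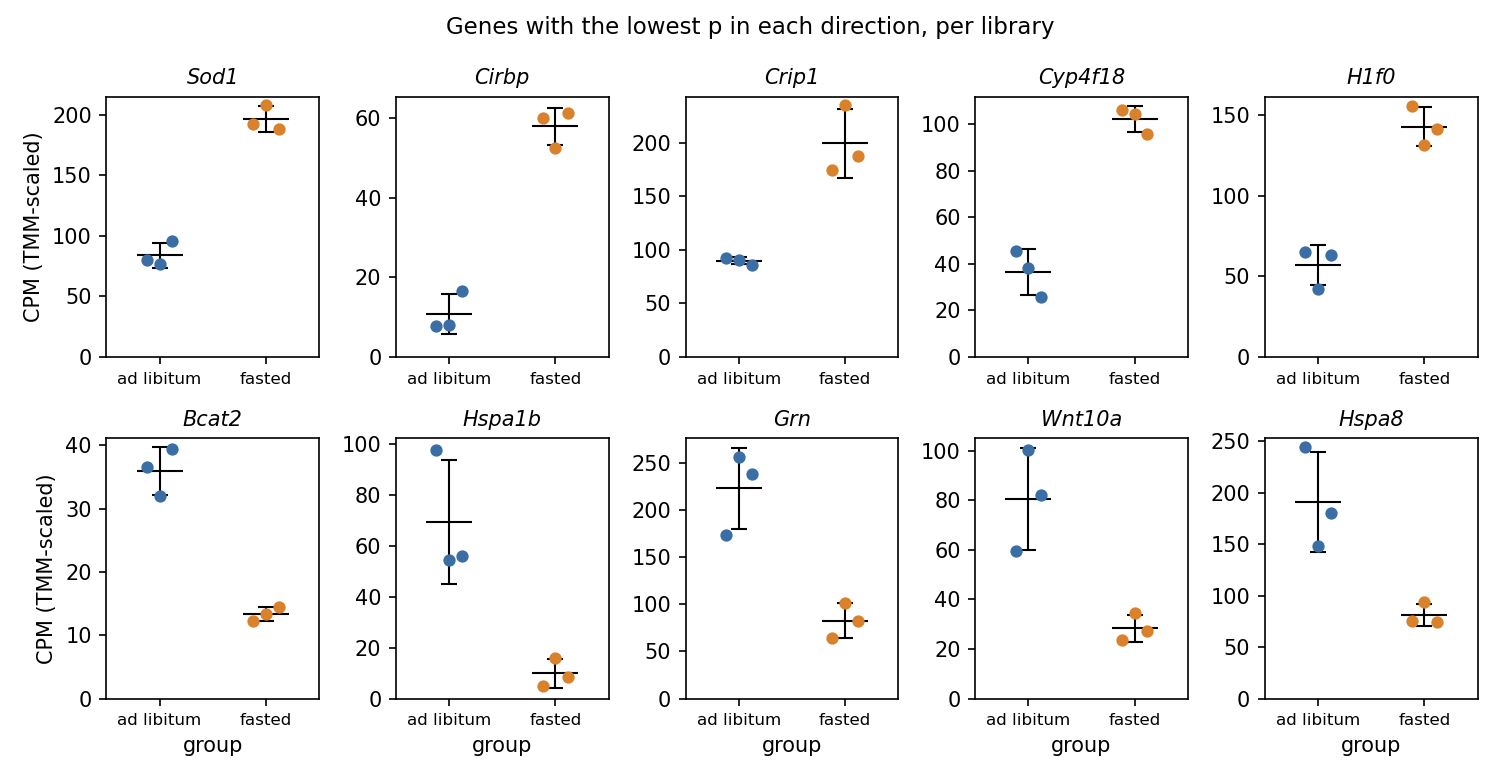
CPM (vertical axis, scaled with TMM factors) in each library of the ad libitum and fasted groups (horizontal axis) for the 5 genes with the lowest p in each direction. Points are libraries, and bars show the mean and SD of n = 3. That the groups do not overlap was a condition for showing a gene. The adjusted p is at least 0.380 for each in edgeR's test, while DESeq2 called all 10.

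As groups, transcripts of glycolysis and of the endoplasmic reticulum (ER) folding machinery were lower in fasted libraries relative to other genes at a preset inter-gene correlation. With an estimated correlation neither list was called (p = 0.0483 for glycolysis and p = 0.273 for the ER list, both adjusted p = 0.978). In the glycolysis list, 15 of 17 measured members had fewer counts in fasted libraries, with a median log2 fold change of -0.48 (camera, adjusted p = 0.0170 over 29 lists). Gapdh was at 196 ± 28.1 CPM in ad libitum and 106 ± 17.7 CPM in fasted libraries (SD, n = 3 each), Gpi1, the glucose-6-phosphate isomerase gene, had a log2 fold change of -0.84 ± 0.29 SE, and Tpi1, the triosephosphate isomerase gene, one of -0.81 ± 0.35. In the list of the unfolded protein response and ER chaperones, 19 of 24 members had fewer counts, with a median of -0.22 (adjusted p = 0.0355). Its members with the lowest p were Hyou1, an ER chaperone (-1.09 ± 0.31), Dnajb9, an ER co-chaperone (-0.63 ± 0.22), and Ern1, which encodes the stress sensor IRE1 alpha and had more counts in fasted libraries (1.07 ± 0.39). No member of either list passed on its own in edgeR's test, over all genes or adjusted over the list alone, while DESeq2 called 1 member of each over all genes (Gapdh, adjusted p = 0.0161, and, chosen after its values were seen, Hsp90b1, 0.0272) and neither without fasted 3. Without ad libitum 1 the adjusted p was 0.0918 for glycolysis and 0.180 for the ER list. The median of the ER list was -0.14 without ad libitum 1 and -0.62 with length offsets, where the median of all genes was -0.25. The ER list was also not called with the strict filter (0.0646), without fasted 3 (0.402) or without both ad libitum 2 and fasted 3 (0.235), while glycolysis was (0.00928, 0.0439 and 0.0133).

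No other list passed in camera's test without length offsets on all libraries, and values are given for them without a call. With length offsets 4 more passed, each lower, and their values are given with each list. Calls of single members over a list alone are from edgeR. Of the members named for the remaining lists, DESeq2 on all libraries called, over all genes and besides Sod1 and Hspa1b, Decr1, Ndufa1, Rps25, Odc1, Top2a, Gabarapl1, Ccr7, Cd37, Bhlhe41, Hspa1a and Retnlg. Of these 11, it called Gabarapl1 without fasted 3, and Ccr7, Top2a and Hspa1a without both ad libitum 2 and fasted 3. Of the gate markers, Sdc1 had a log2 fold change of -0.01 ± 0.24 and Tnfrsf13b one of 0.48 ± 0.20. Tnfrsf13b was at 135 ± 24.1 CPM in ad libitum and 189 ± 21.8 CPM in fasted libraries, and the groups did not overlap. In edgeR's test its unadjusted p was 0.0485 and its adjusted p 0.710. Jchain, the joining chain of IgM and IgA, was at 0.02 ± 0.56. Of 19 plasma cell identity genes, 9 had more and 10 fewer counts in fasted libraries (median -0.01, camera adjusted p = 0.575). Derl3, of ER-associated degradation, was at -0.58 ± 0.19, Slamf7, a surface receptor, at -0.47 ± 0.18 and Ly6c2 at -0.64 ± 0.26. The 29 genes of the translocon, signal peptidase and oligosaccharyltransferase had a median of -0.05 (adjusted p = 0.546, and lower at 0.0214 with length offsets), with Dad1 at -0.40 ± 0.17. Among 13 anti-apoptotic and survival receptor genes (median -0.03, adjusted p = 0.939), Tnfrsf13c, the BAFF receptor gene, was at 0.60 ± 0.19, Il6st, the shared receptor subunit of the IL-6 family, at -2.51 ± 0.89 and Birc3 at -0.97 ± 0.39. The 15 pro-apoptotic genes had a median of 0.01 and a mean of -0.18 (adjusted p = 0.830), with Pmaip1, the NOXA gene, at 1.87 ± 1.15.

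Lists tied to nutrients and hormones also stayed short of the threshold. The ATF4 targets of the amino acid response had 13 of 18 members with more counts in fasted libraries (median 0.47, adjusted p = 0.235, or 0.0489 without ad libitum 3). Their member with the lowest p, the serine synthesis gene Psat1, had fewer (-1.53 ± 0.46), ahead of Eif4ebp1 (0.78 ± 0.29) and Mthfd2 (1.33 ± 0.58). Of 12 glucocorticoid response genes 10 had more counts (median 0.37, adjusted p = 0.502), among them the metallothionein gene Mt1 (1.08 ± 0.36) and Tsc22d3, which encodes GILZ (0.74 ± 0.29). The FoxO and growth factor withdrawal list had a median of 0.39 (15 genes, adjusted p = 0.939), with Cited2 at 0.62 ± 0.21 and Ccng2 at -1.47 ± 0.55. Fatty acid oxidation, ketone body and PPAR genes had a median of 0.31 while their camera direction was lower (17 genes, adjusted p = 0.939). Ucp2, a mitochondrial carrier, was at -0.73 ± 0.24 and Decr1 at -1.92 ± 0.78. Cholesterol genes had a median of -0.14 (19 genes, adjusted p = 0.939). Fatty acid synthesis genes had a median of -0.22 (10 genes, adjusted p = 0.732), with Scd2 at -2.78 ± 1.35 and Fasn at -2.28 ± 1.33.

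Nuclear and mitochondrial genes of the respiratory chain were tested as separate lists, and the difference between them was not tested. Of 72 nuclear-encoded oxidative phosphorylation genes 52 had more counts in fasted libraries (median 0.20, adjusted p = 0.260), including Ndufa1 (0.63 ± 0.18) and Cox7b (0.60 ± 0.21) but not Uqcrb (-0.81 ± 0.22). This list was called higher without ad libitum 2 (adjusted p = 0.0350), without fasted 2 (0.0140) and without both ad libitum 2 and fasted 3 (0.0133). Its camera direction was lower without ad libitum 1, without fasted 1 and with length offsets, and its adjusted p ranged from 0.0133 to 0.983 over 16 alternatives. Of 8 mitochondrially encoded protein genes 7 had fewer (median -0.33, adjusted p = 0.137), with mt-Nd5 at -0.56 ± 0.21, and the list was called lower without ad libitum 3 (0.0489) and with length offsets (0.0214). Cytosolic ribosomal protein genes had a median of 0.06 (82 genes, adjusted p = 0.939), with Rps25 at 0.91 ± 0.18. They were called higher without fasted 2 (0.0289) and without both ad libitum 2 and fasted 3 (0.0471), but lower with length offsets (0.0214). Ribosome biogenesis and MYC targets had a median of -0.03 (21 genes, adjusted p = 0.235). Their lowest-p members were Odc1, the ornithine decarboxylase gene (-1.35 ± 0.32), Ppan (-1.16 ± 0.37) and Gnl3 (-0.79 ± 0.29). Cell cycle genes had a median of 0.00 (29 genes, adjusted p = 0.939), and Top2a (1.93 ± 0.54) and Mki67 (-0.82 ± 0.26), both proliferation markers, differed in sign.

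Autophagy and lysosome genes had a median of 0.13 (25 genes, adjusted p = 0.732), with Gabarapl1 at -2.40 ± 0.68, Gabarap at -0.68 ± 0.21 and Map1lc3b, an LC3 gene, at 0.63 ± 0.22. The 13 antioxidant genes had a median of 0.17 (adjusted p = 0.546), and Sod1 was the 1 member that passed adjusted over the list alone. Type I interferon genes had a median of -0.13 (11 genes, adjusted p = 0.830). In the homing, adhesion and egress list (20 genes, median 0.22, adjusted p = 0.941), Ccr7, a receptor for lymph node chemokines, was at 0 CPM in all ad libitum libraries and at 3.11 ± 2.41 CPM in fasted libraries. The tetraspanin genes Cd37 and Cd9 were at -0.65 ± 0.18 and 0.64 ± 0.23. Circadian clock genes had a median of -0.02 (13 genes, adjusted p = 0.939), with the repressor gene Bhlhe41 at -1.30 ± 0.32. The list of immediate early and heat shock genes had a median of 0.08 but a mean of -0.18 and a lower camera direction (19 genes, adjusted p = 0.150). It was called lower without ad libitum 2 (0.0127), without fasted 2 (0.00782) and with length offsets (0.00815). Hspa1b, Hspa1a (-2.36 ± 0.63) and Hsp90aa1 (-0.79 ± 0.24) had fewer counts in fasted libraries, while 11 members had more. Hspa1b passed adjusted over the list alone. Hspa1a and Hspa1b are near-identical copies and reads may be split between them.

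**Figure D3:**
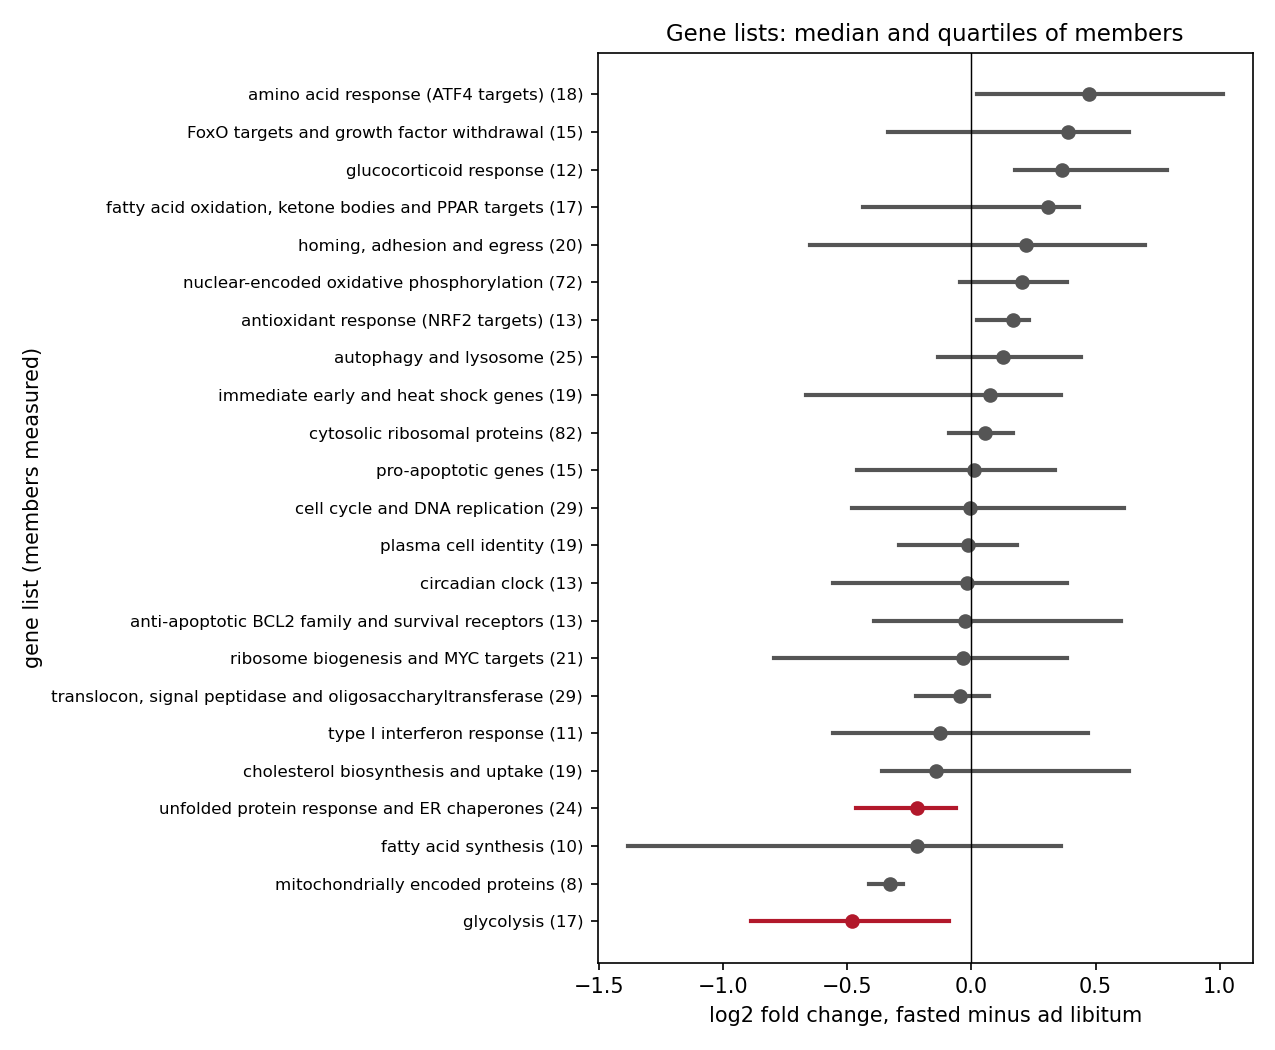
Median (point) and quartiles (line) of the members' log2 fold change, fasted minus ad libitum (horizontal axis), for the 23 lists of functions (vertical axis, measured members in brackets). The lists called by camera at adjusted p under 0.05 are red, with medians of -0.48 (glycolysis) and -0.22 (unfolded protein response and ER chaperones).

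Markers of other cell types of the marrow were present at low to moderate levels, and none of their 6 tested lists passed with all libraries. The neutrophil gene S100a8 was at 166 ± 42.5 CPM in ad libitum and 275 ± 28.2 CPM in fasted libraries, and Retnlg at 14.1 ± 1.51 and 30.4 ± 5.60 CPM. The 13 neutrophil genes had a median of 0.08 and a mean of -0.33 (adjusted p = 0.546), and Retnlg passed adjusted over the list alone. The B cell and MHC class II list had a median of 0.10 (13 genes, adjusted p = 0.742). The erythroid list had 5 of 6 members with more counts (median 0.82, adjusted p = 0.260, but higher at 0.0419 without ad libitum 2 and 0.0172 without fasted 2), with Hbb-bs at 11.7 ± 5.07 and 28.5 ± 15.5 CPM. The T and NK cell list had 4 of 5 (median 1.04, adjusted p = 0.235), with Cd3d at 0.139 ± 0.241 and 1.47 ± 0.961 CPM. Monocyte and macrophage genes had a median of -0.34 but a mean of 0.41 (11 genes, adjusted p = 0.939), and plasmacytoid dendritic cell genes a median of -0.04 (5 genes, adjusted p = 0.830), with Ccr9 at 1.69 ± 0.66. Fewer than 5 members were measured for pro-B and pre-B cells (3 genes, median -0.02), megakaryocytes and platelets (1 gene, 1.39), eosinophils, basophils and mast cells (4 genes, 0.90), stromal, endothelial and fat cells (3 genes, 1.34) and stem and progenitor cells (4 genes, -0.48), which were not tested.

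Immunoglobulin transcripts were compared between the groups as shares of counts. Immunoglobulin genes took 70.4% ± 2.58 of counts in ad libitum and 69.7% ± 1.86 in fasted libraries (SD, n = 3 each, exact two-sided permutation test p = 0.8). Of the heavy-chain constant-region counts, Ighm (IgM) took 54.9% ± 17.8 and 52.0% ± 12.4 (exact p = 0.8), and Igha (IgA) 34.1% ± 14.6 and 35.8% ± 7.50 (exact p = 0.9). Ighg2b took 5.85% ± 3.60 and 8.93% ± 5.14 (exact p = 0.4), Ighg1 2.16% ± 1.33 and 1.58% ± 0.0984 (exact p = 0.5) and Ighg3 1.66% ± 0.889 and 0.890% ± 0.103 (exact p = 0.4). The share of Ighg2c was 1.39% ± 0.338 and 0.760% ± 0.0785 and that of Ighd, of IgD, 0.00205% ± 0.000693 and 0.00622% ± 0.00204. Neither overlapped between the groups (exact p = 0.1 each, the smallest that 3 against 3 libraries can give; 0.4 after Benjamini-Hochberg adjustment). In edgeR's test Ighg2c had a log2 fold change of -0.95 ± 0.28 and Ighd one of 1.53 ± 0.60 (adjusted p = 0.481 and 0.681), and DESeq2 called Ighg2c but not without fasted 3. Lambda light chains took 6.78% ± 2.32 and 10.5% ± 3.17 of the light-chain constant-region counts (exact p = 0.2). The effective number of heavy-chain variable segments was 42.3 ± 2.88 and 41.2 ± 4.52 (exact p = 0.8).

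**Figure D4:**
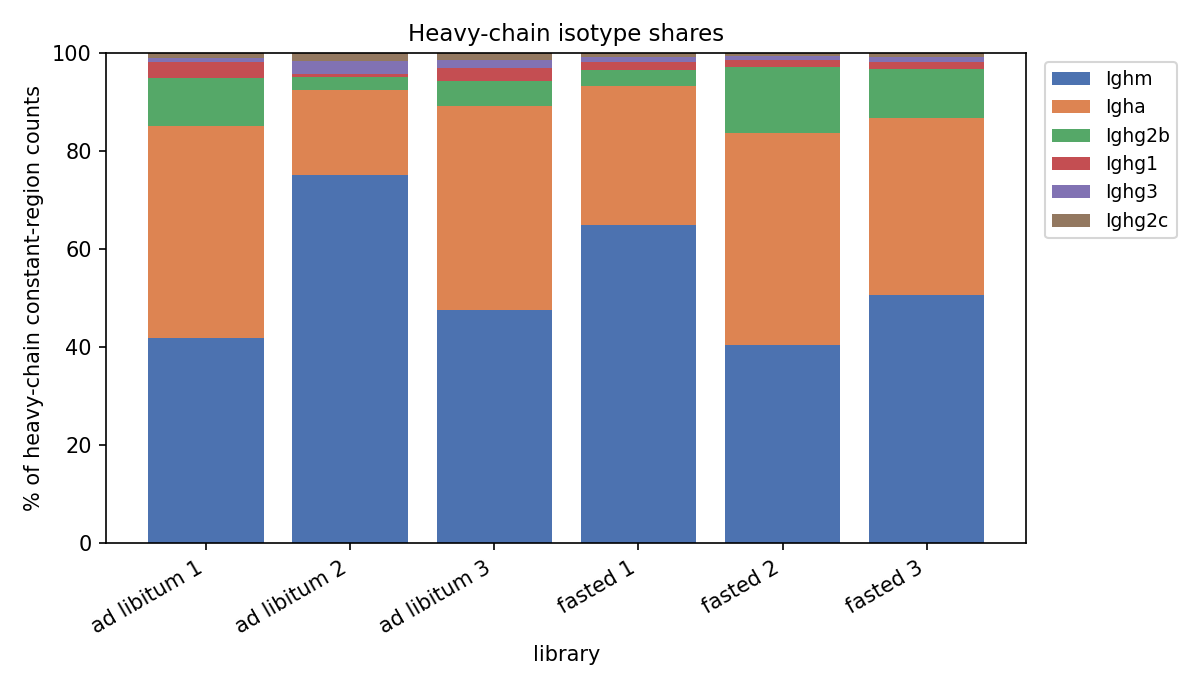
Share of heavy-chain constant-region counts (vertical axis, percent) taken by each of 6 isotype genes in each library (horizontal axis); Ighd and Ighe, both under 0.01%, are not drawn. Ighm ranges from 41.9% to 75.1% in ad libitum and from 40.4% to 65.0% in fasted libraries.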

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

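The alternatives that leave out both doubted libraries or the ribosomal RNA genes, the length offsets and the block with an estimated correlation for the lists, and DESeq2 and quality weights without fasted 3 were chosen after seeing the data. The number of genes called was 0 in all alternatives except the test without a filter (8 genes), DESeq2 (354, or 154 without fasted 3 and 144 without ad libitum 2 and fasted 3) and quality weights with all libraries (25). The cause was not tested, though quality weights gave fasted 3 a weight of 6.93 and ad libitum 2 one of 0.180, and without fasted 3 they called 0. Leaving out each library in turn gave 0 genes each time, with 428 (without fasted 3) to 1068 (without ad libitum 2) at an unadjusted p under 0.05. With the replicate number as a block, 0 genes and 2 lists were called, with 430 genes at an unadjusted p under 0.05. Same-numbered libraries had deviations that correlated at -0.067, -0.019 and 0.050, so the numbers were not read as pairs. The number of lists called was 2, and it was 0 with an estimated correlation, 0 with fry (9 when members could move in either direction), 0 with the replicate block and an estimated correlation, 1 with the strict filter, 6 with gene length offsets and 0 to 6 when a library was left out (0 without ad libitum 1, 6 without fasted 2). Length offsets also turned the cytosolic ribosomal protein list to lower (adjusted p = 0.0214), while it was called higher without fasted 2 (0.0289) and without both doubted libraries (0.0471), against 0.0214 to 0.983 over its 16 alternatives. They moved the median of all genes from 0.05 to -0.25 on the log2 scale, and the cause was not tested. Of 461 list results under alternatives, 435 kept their direction and side of the threshold or differed in direction with neither value past it (48), 11 lost and 14 gained a call and 1 reversed. Of 2810 results for named genes, 2753 did so (42 differing in direction with neither past it), 57 gained a call and 0 reversed. These tallies do not measure stability, since most results had no call to lose. Among the lists a call could be lost only by the 2 called ones, over 16 alternatives each, and all 11 losses were theirs. Of the named genes 0 were called in edgeR's test with its filter, so none could lose a call. Leaving 1 of 3 libraries out cannot move a mean by 1 SD, so it says nothing about the stability of shares and diversity. Genes outside immunoglobulin held 6513685 to 7964572 counts per library. Thinned to the smallest library, 0 genes were called and 710 had an unadjusted p under 0.05, against 722. Thinned to equal depth, ad libitum 2 still had 9194 such genes against 10898 to 13667.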

Other observations

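The tests of shared material, of the glycolysis list and of immediate early genes, and all counts of splits except that for genes called, were chosen after the result was seen. The list of further heat shock factor targets was prompted by heat shock genes already seen lower in these libraries. Its test was set before the values of its own members were looked at. Of 234 immunoglobulin variable, diversity and joining segments tested, 64 (27.4%) had an unadjusted p under 0.05 in edgeR's test, 24 with more and 40 with fewer counts in fasted libraries, against 655 of 10154 genes outside immunoglobulin (6.45%). Segments were also above other genes in each of the 9 other splits of the libraries (2.14% to 17.9% against 0.286% to 2.93%), so the excess over other genes is not particular to the groups. The real split gave 27.4%, the highest other 17.9% (1 of 10), and 10 splits are too few for a share under 0.05. The real split is also the only one that keeps fasted 3 with both fasted 1 and fasted 2, so shared material could raise its value. Igkv4-69, chosen after its values were seen, had 51, 169 and 134 counts in the ad libitum libraries and 2736, 11228 and 3561 in the fasted libraries, and Igkv1-122 had 15010, 14359 and 6835 against 771, 2819 and 1160. Of the 354 genes called by DESeq2, 31 were such segments. Fasted 3 is not sure to be a separate sample.

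Heat shock chaperones had fewer counts in fasted libraries and the cold-inducible genes Cirbp and Rbm3 more (log2 fold change 2.42 ± 0.35 and 1.11 ± 0.24), and as a hypothesis this may reflect a lower body temperature or less heat shock factor activity in fasted mice. Further heat shock factor targets and chaperonin subunits had a median of -0.81 (quartiles -1.23 and -0.31), with 20 of 23 lower, among them Fkbp4 (-1.34), Chordc1 (-1.34) and Dnaja1 (-1.23). On their own 0 passed the threshold in edgeR's test and 4 in DESeq2 (these 3 and Cct6a), or 0 in DESeq2 without fasted 3. Camera gave an unadjusted p = 3.62e-09 at the preset correlation and, with an estimated correlation, p = 0.0174. The list was prompted by related genes seen lower in these same libraries, so these p-values are not independent evidence for the pattern. Over 25 alternatives the median lay between -1.18 and -0.64, and without the 2 members that also stood in a list fixed earlier it was -0.78. A difference in handling stress could lower immediate early genes too, but their median was 0.25 (quartiles 0.07 and 0.49), with 11 of 14 higher. That they were higher depends on the setting: over 25 alternatives the median lay between -0.16 and 0.33, and it was 0.01 without both ad libitum 2 and fasted 3 and -0.10 (quartiles -0.49 and 0.11) without fasted 2. None of these is a fall like that of the heat shock factor targets. Fos, Jun and Junb had high counts over all libraries (average log2 CPM 9.92, 9.18 and 7.85), while Nr4a1 and Atf3 were low (0.352 and 0.148). If the high ones were near their maximum in both groups, a difference in handling stress need not lower them, so handling stress stays open. Heat during handling was not tested and stays open. Other splits of the libraries also gave small p-values, the lowest 0.000554 and 4 of 9 under 0.05. Of the 10 splits 1, the real one, gave p as small as 3.62e-09, and 10 are too few for a share under 0.05. The real split is also the only one that keeps fasted 3 with both fasted 1 and fasted 2, so shared material could make its p smaller.

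Fasted 3 held the transcripts of fasted 1 and fasted 2. Over the 3866 genes above 200 counts in fasted 1 the lowest ratio of fasted 3 to fasted 1 counts was 0.328. Over 4528 such genes of fasted 2 it was 0.151, whereas it was at most 0.00323 in the 28 other ordered pairs of libraries. The lowest ratio rests on the most extreme gene of each pair. At the 1st percentile the ratio was 0.459 for fasted 1 and 0.251 for fasted 2, against 0.239 for ad libitum 1 to ad libitum 3 counts. Ad libitum 1 also held 23 of 32 genes private to ad libitum 3. The 1st percentile thus sets fasted 1 apart but hardly fasted 2. Shared RNA, cDNA or reads, such as a pool, could give these values. Depth or complexity of fasted 3 is argued against by the genes private to an ad libitum library, of which fasted 3 held 27.7% (28 of 101, exact 95% interval 19.3% to 37.5%), against 100% of the 109 private to fasted 1 or fasted 2 (96.7% to 100%). A common response to fasting would make fasted 1 resemble fasted 2, but they correlated at 0.687, below both of their correlations with fasted 3. Each ad libitum library also had its highest correlation with fasted 3 (ad libitum 1 at 0.855, ad libitum 2 at 0.699, ad libitum 3 at 0.836). High correlation with fasted 3 is thus not particular to fasted libraries, and the correlations alone do not decide on a common response. Modelled as a sum of the other libraries, fasted 3 had its largest weights for fasted 1 (0.436) and fasted 2 (0.331); at which step material could have been shared stays open.

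The lower glycolysis list was examined for 3 technical explanations. It stayed called with gene length offsets (adjusted p = 0.00815), which moved genes unequally (SD of the shift 0.30 on the log2 scale) and so argue against a length trend as the whole cause. Removing immunoglobulin genes (0.00438) moved nearly all other genes alike (SD of the shift 0.00416), so it says nothing about them as a cause, which stays open. The call was lost without 1 library: without ad libitum 1 the adjusted p was 0.0918, and the median moved from -0.48 (quartiles -0.89 and -0.09) to -0.37 (-0.92 and -0.01) with 13 of 17 members still lower. Without each of the other 5 libraries the call was kept (0.00597 to 0.0489). The shift of the median was not particular to ad libitum 1: it was -0.33 without fasted 3, -0.36 without fasted 1 and -0.38 without ad libitum 3, where 11 of 17 members were lower. Its adjusted p ranged from 0.00438 to 0.983 over 16 alternatives, and dependence on ad libitum 1 and an effect of fasting both stay open.

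With 3 against 3 libraries there are 10 splits, too few for a share under 0.05. The count of genes called by edgeR was 0 in the real split and at most 0 in the others, so 10 of 10 splits gave as many. The count at an unadjusted p under 0.05 was 722, against at most 324 in the others (1 of 10), and that of genes called by DESeq2 was 354, against at most 107 (1 of 10). The number of lists called was 2, against at most 6 in the others, and 5 of 10 splits gave as many. With an estimated correlation it was 0 in all 10 splits, so whether the calls in other splits come from structure among the libraries or from the preset correlation stays open.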
